A study of Mus musculus with 6 samples.

How the data were processed

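RNA from the pancreas of Sox4 knockout embryos and of wild-type littermates at embryonic day 12.5 was measured on 6 spotted arrays with 2 channels each, wild type in channel 1 and knockout in channel 2, per the labels. Per the label of arrays 1 and 2, tissue was pooled into 2 groups for RNA isolation, the RNA was amplified linearly, and the targets were labelled indirectly. The label of the other arrays does not repeat this. The authors' deposited table gives log2 ratios, a base set by its ceiling value, which is log2 of 1e+05. Scanner, background correction, normalization, dyes and direction are not given in the sources used here. Direction therefore stays unknown, and any centring could be judged only from the values below. Signal over background is unknown because the intensities were not used here. The number of arrays limits the precision.

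The medians of the deposited values were -0.006, 0.08, 0.147, 0.072, 0.203 and 0.147 on arrays 1 to 6. The ceiling value stood at 40 to 257 probes per array and was treated as missing. Of ratios beyond 3 in log2 size, 60.9% to 88.5% per array were whole numbers or their inverses within 6e-04 in log2. After a shift of 0.037 the share was 0% to 1.7%. Ratios of small whole-number intensities can take such values, and this argues against a scaling factor on most of these large ratios. Quotients of whole numbers up to 20, the measure used below, made up 22.6% of the values of all tested probes. The same shift left 11.2%. Every array was centred on its median, and probes with a value on at least 4 arrays were kept, 21247 of 21888.

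Of the probes in the table, 18388 had 1 gene symbol, 66 several and 3434 none in the platform annotation. Symbols were looked up by Entrez ID in a RefSeq gene table for 17786 of the probes with 1 symbol, and 602 kept the annotation's symbol. Probes with several symbols were not named. The tested probes with 1 symbol numbered 17922 and covered 10818 genes, and different probes of a gene were reported apart.

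Differences were tested two-sided against 0 with limma 3.58.1 (lmFit and eBayes, intercept only) in R 4.3.3, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9. Gene lists were tested with camera's preset correlation of 0.01 on the moderated statistics of gene means, adjusted over the 20 lists with at least 3 measured genes of 21 lists fixed. Lists were pancreatic progenitor factors, endocrine factors, islet hormones and granules, acinar, epithelium and duct, mesenchyme, endothelium, erythroid, leukocyte, neuron and neural crest, liver, stomach and intestine, SoxC, cell cycle, cell death and p53, Notch, Wnt, hypoxia and glycolysis, immediate early and heat shock, X and Y chromosome, and ribosomal proteins. The lists, the test and the rule for named genes were fixed before the data were examined.

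Named genes were Sox4, Sox11, Sox12, Neurog3, Pdx1, Ptf1a, Neurod1, Ins1, Ins2 and Gcg where measured. To these were added the 12 probes with the largest mean on each side among probes with 1 symbol, at least 4 arrays, an adjusted p under 0.05 and the same sign on every measured array. Up to 4 members of each list past the threshold were also named, or the member with the smallest p where none passed. Other genes named outside this rule were chosen after their values were seen: the Alb, Ttr, Apoc1, Vtn, Apoc3, Apoh, Hpx and Rbp4 values, Pax6, Hes6, Rps23rg1, Rps19bp1, the genes in the neighbouring wells with Six6, the X-linked genes and those of the size test.

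The fit was tested on simulated data for 21247 probes with known changes. The noise was normal, with the SD and missing values of each probe, and independent between probes and arrays. A log2 change of 0.5, 1 or 2 was given to 67, 67 or 66 probes and recovered in 19.4%, 73.1% or 81.8% of them. There were 4 calls among unchanged probes and 0 calls when nothing was changed. The adjustment depends on how many probes change, so these shares need not hold for the real arrays. The liver list of 12 genes moved by -0.5 was recovered with noise that was independent between genes. Correlation between arrays or genes was not simulated, so the simulation does not show how the tests behave under it.

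Alternatives were no centring, scale or quantile normalization, other filters on missing values, array weights, robust eBayes, a test against a log2 change of 0.2, 1 value per gene, 1 probe per gene, an estimated correlation, list members counted by a mean of at least 0.5 in size, and each array left out in turn. Alternatives chosen after seeing the data were the ceiling kept as a value, arrays 3 to 6 or 1 and 2 alone, the array set as a term, and the removal of probes whose ratios were mostly quotients of whole numbers.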

Results

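The study compared RNA from the embryonic pancreas of mice that lacked Sox4 with RNA from wild-type littermates at embryonic day 12.5. Sox4 is a transcription factor of the SoxC family, and at this stage the pancreas is a branching epithelium in which the first endocrine cells are forming. The question, per the labels, was which genes change their expression across the genome when Sox4 is missing. Each of 6 spotted arrays was hybridised with both RNAs, wild type in channel 1 and knockout in channel 2, and the deposited table holds 1 log2 ratio per probe and array for 21888 probes. Values were missing for 439 to 1654 probes per array. The ratio is read here as knockout over wild type, which is only likely, since the dyes and the direction are not given in the sources used here and the basis is the channel order and the titles. Tissue was pooled into 2 groups before RNA isolation, per the label of arrays 1 and 2, so the arrays may be repeats of 1 knockout and 1 wild-type pool. All p-values therefore compare these RNA pools against the spread between arrays, which may be technical, and not the genotypes across animals. Per the labels, each RNA was in the same channel on every array. A bias of a probe between channels therefore cannot be told apart from a difference between the RNAs.

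Neither probe of Sox4 itself was past the threshold. Its probe MMC02H11 had a mean log2 ratio of -0.03 ± 0.25 (SD, n = 6 arrays), with array values of -0.16, 0.41, -0.35, 0.01, -0.01 and -0.06 and a limma adjusted p of 0.892. Its probe MMC03H11 had a mean of -0.09 ± 0.13 (SD, n = 6), with an adjusted p of 0.446. Where these probes lie relative to the deleted part of the gene is not given in the sources used here, so Sox4 does not check the direction or the labels, and the samples are called the RNA labelled knockout and the RNA labelled wild type. Among the other SoxC genes, the Sox12 probe was at -0.02 ± 0.24. Of 10 Sox11 probes, 1 was past the threshold, at -0.71 ± 0.36, and the others ranged up to 1.32, so the probes of this gene disagreed. The probe at 1.32, MMC03H08 (n = 4), had 4.01 on array 5 and was at 0.42 without it.

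In the comparison of the 2 RNAs, 1166 of 21247 tested probes were past an adjusted p of 0.05, 416 with a mean log2 ratio above 0 and 750 with a mean under 0. They named 347 genes above 0, 536 genes under 0 and 5 genes with probes on both sides. Among probes with a gene name that were past the threshold, the furthest under 0 were those of Hsd3b1, Afp, Acin1, Eya2, Dach1, Fabp4, Six5, Akr1c19 and Mt2. Afp, the alpha-fetoprotein of fetal liver and yolk sac, was 4.16-fold lower in the RNA labelled knockout at its lowest probe, with means of -2.06 ± 0.22, -2.05 ± 0.25 and -1.90 ± 0.22 at 3 of its 4 probes (SD, n = 6) and an adjusted p of 0.00141 at each, while the remaining probe was at 0.01. Fabp4, a fatty acid carrier, was at -1.34 ± 0.11 with an adjusted p of 0.00141, and Mt2, a metallothionein, was at -1.24 ± 0.12 with an adjusted p of 0.00196. All 6 arrays were under 0 for each of these Afp probes, Fabp4 and Mt2.

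Hsd3b1, an enzyme of steroid hormone synthesis, was at -2.27 ± 0.59 with an adjusted p of 0.0126. Akr1c19, an aldo-keto reductase, was at -1.28 ± 0.26 with an adjusted p of 0.0111. A probe named Acin1, ZX-00139D19, was at -1.99 ± 0.25, while the other probes of that gene were at 0.02 and 0.39. Its array values of -1.81, -1.56, -2.21, -2.08, -2.15 and -2.13 lay close to those of the Afp probe PX-00616G12, at -1.92, -1.63, -2.36, -2.15, -2.13 and -2.11. Eya2 was at -1.99 ± 0.61, Six5 at -1.29 ± 0.71 and Dach1 at -1.63 ± 0.39 (n = 4) and -1.53 ± 0.91 (n = 6). Per the probe names, these transcriptional regulators sit in wells of 1 source plate that follow each other in well order. The wells, D12 and E01 to E08, are called neighbouring here. All 9 probes in them, from Dach1 to Mafa, had means under 0. The wells just before and after, D11 and E09, were also under 0, at -0.57 and -0.32, so the edges of the block are not sharp.

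**Figure D1:**
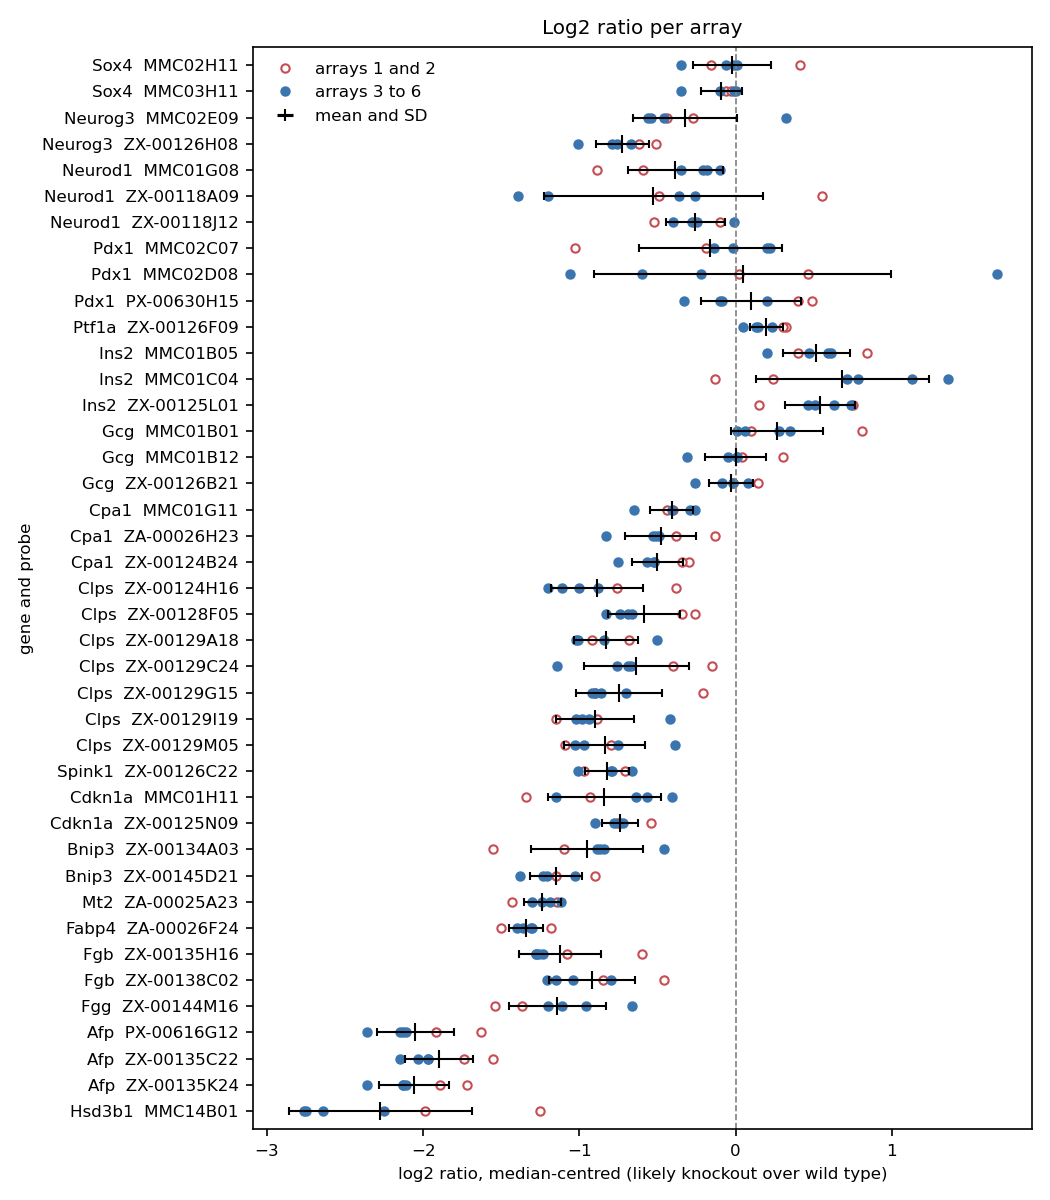
Log2 ratio of each array (x axis) for named probes (y axis), with open circles for arrays 1 and 2, filled circles for arrays 3 to 6, and the mean with its SD. The Afp, Fabp4 and Mt2 probes lie under 0 on all 6 arrays, and the Sox4 probes lie around 0.

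Above 0, the 12 largest ratios of probes with a gene name that were past the threshold belonged to Irak1bp1, Calb1, Ckb, Ccsap, Kif15, Edem2, Serpinb9c, Smim41, Unc5b, Zcrb1, Rer1 and Hjv, from 2.23 ± 1.13 for Irak1bp1 to 1.48 ± 0.74 for Hjv. Other probes of Irak1bp1, Ckb, Edem2, Rer1 and Hjv reached values under 0, down to -1.23 for Irak1bp1. Calb1 encodes a calcium-binding protein, Ckb a creatine kinase and Kif15 a mitotic motor protein. Of the 68 probes past the threshold at 1 or more above 0, 76.5% had ratios that were mostly quotients of small whole numbers, against 30% of the 30 such probes at -1 or under and 18.6% of all tested probes. Other probes above 0 had smaller and tighter ratios: Cdc6, which licenses DNA replication, was at 0.79 ± 0.14 with an adjusted p of 0.0126 at one probe and 0.33 at the other, and Gsk3b, a kinase of the Wnt pathway, was at 0.53 ± 0.13 with an adjusted p of 0.0259 at 1 of 4 probes. The other Gsk3b probes were at 0.73, 0.20 and -0.10.

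Among endocrine transcription factors, 1 of 11 measured genes was past the threshold. Neurog3, which starts the endocrine programme, was at -0.73 ± 0.17 (SD, n = 6; adjusted p 0.0203) at one probe, a 1.65-fold lower ratio with all 6 arrays under 0. Its other probe, in the well right after the neighbouring wells above, was at -0.32 ± 0.33, with an adjusted p of 0.164. This probe is therefore not clear of a possible effect of plate position. Neurod1, a later endocrine factor, had means of -0.39, -0.53 and -0.26 at its 3 probes, none past the threshold. This list had 1 gene above 0 and 3 under 0 adjusted over the list alone, and its adjusted camera p was 0.65. The 3 were Neurog3, Mafa at a probe in the neighbouring wells above, and Pax6 at -0.28, with another Pax6 probe at 0.34. The gene above 0 was Hes6, at probes at 0.33 and 0.43, with its other probes from -0.26 to 0.52.

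Among islet hormone and secretory granule genes, 2 of 15 measured genes were past the threshold, both above 0. Ins2, an insulin gene, was at 0.54 ± 0.23 and 0.52 ± 0.22 at 2 probes, with adjusted p of 0.0363 and 0.0373, and at 0.68 ± 0.55 at its remaining probe, with an adjusted p of 0.091. Pcsk1n, an inhibitor of prohormone processing, was at 0.70 ± 0.19 (n = 5) at one probe and at -0.52 at the other. The Gcg probes, for glucagon, were at 0.27, 0.00092 and -0.03, with none past the threshold. Counted as adjusted over the list alone, 4 genes were above 0 and 2 under 0, and the list as a whole had an adjusted camera p of 0.416.

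Of 14 measured progenitor transcription factors, 3 were past the threshold under 0 and 1 above 0. Nr5a2, a nuclear receptor of the exocrine programme, was at -0.91 ± 0.36, Foxa1 at -0.65 ± 0.31 and Foxa3 at -0.64 ± 0.17, while the other Foxa3 probe was at -0.15. Hhex was at 1.30 ± 0.55 (n = 5), with all of its ratios quotients of small whole numbers. Pdx1, needed for pancreas formation, had means of -0.16, 0.05 and 0.10, and Ptf1a, of the exocrine lineage, was at 0.20 ± 0.11 with an adjusted p of 0.127. There were 3 genes past it above 0 and 4 under 0 adjusted over the list alone, and the adjusted camera p was 0.65.

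Acinar genes, for digestive enzymes and their partners, had 4 of 18 measured members past the threshold under 0 and none past it above 0. Clps, the colipase, was past it at 7 of 9 probes, from -0.90 ± 0.25 to -0.59 ± 0.23, and the others reached 0.12. Cpa1, a carboxypeptidase, was past it at all of its 3 probes, at -0.50, -0.48 and -0.41. Spink1, a trypsin inhibitor, was at -0.82 ± 0.14 at one probe and -0.26 at the other, and Pla2g1b was at -0.39 ± 0.16 at 1 of 10 probes that reached up to 0.26. A total of 7 members passed under 0 adjusted over the list alone. The list did not pass the test, with a camera p of 0.0153 and an adjusted p of 0.125.

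The liver list was the only one of 20 tested past the threshold, with an adjusted camera p of 2.3e-05, and with an estimated correlation it did not pass (adjusted p = 0.158). Of its 12 measured genes, 6 were past the threshold under 0 and none above 0: Afp, Fgb, Fgg, Ambp, Apoc1 and Vtn. Fgb and Fgg, chains of fibrinogen, were at -1.12 ± 0.26 and -1.14 ± 0.31, and Ambp, a secreted plasma protein, was at -0.77 ± 0.10. Alb, for albumin, was at -0.29 ± 0.12 with an adjusted p of 0.0622, and Ttr was at -0.18 and -0.21. Vtn passed at 1 of 2 probes, at -0.94, with the other at -0.06. The list's median was -0.39 (-0.25 with 1 probe per gene), under 0 on each array from -0.66 to -0.32, while Apoc3, Apoh and Hpx had means of 0.13, 0.08 and 0.03. Adjusted over the list alone, 7 members passed under 0.

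**Figure D2:**
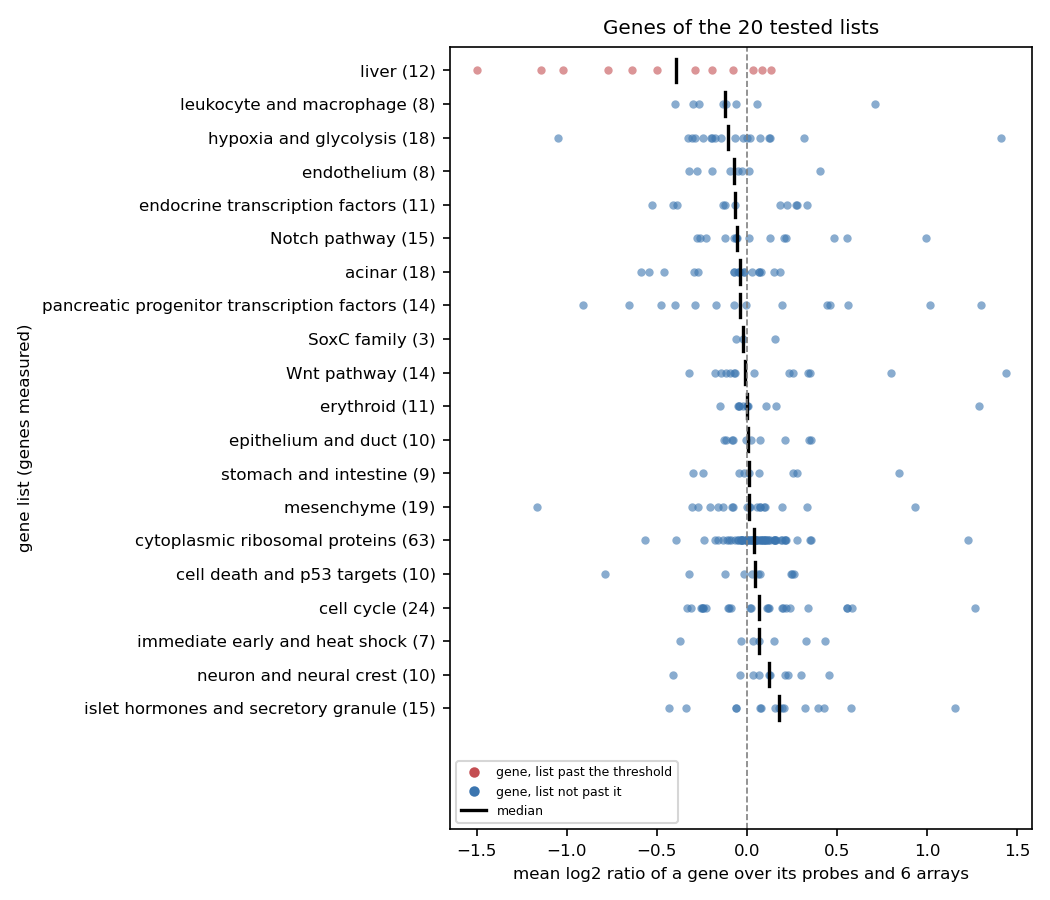
Mean log2 ratio per gene (x axis, points) in each of the 20 tested lists (y axis, with the number of genes measured), with a bar at the median of the list. The liver list, in red, has a median of -0.39, and the other medians lie between -0.12 and 0.18.

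Genes that respond to low oxygen, with glycolysis genes, had 3 of 18 measured members past the threshold under 0 and none past it above 0. Bnip3, a mitochondrial protein induced in low oxygen, was at -1.15 ± 0.17 and -0.95 ± 0.36 at its 2 probes. Tpi1, a glycolytic enzyme, was past it at 3 of 4 probes, at -0.48, -0.47 and -0.33, and Ankrd37 was at -0.32 ± 0.10 at 1 of 2 probes. The camera p of this list was 0.0188, with an adjusted p of 0.125, and 5 members passed under 0 adjusted over the list alone.

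In the cell cycle list, 4 of 24 measured genes were past the threshold above 0 and 1 under 0. Cdk4 was at 0.51 ± 0.20 and Ccnd2 at 0.46 ± 0.19, each at 1 of several probes that reached down to -0.18 and -0.14, and Ccnd1, also a D-type cyclin, was at -0.57 ± 0.16 at one probe and -0.05 at the other. Cdkn1a, an inhibitor of the cell cycle and a p53 target, was past the threshold at both probes, at -0.74 ± 0.12 and -0.84 ± 0.36, the 1 member past the threshold among 10 measured genes of cell death and p53. Adjusted over the list alone, the cell cycle list had 7 genes past it above 0 and 4 under 0, and the cell death list had 1 on each side. Neither passed camera, with adjusted p of 0.886 and 0.867.

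In the neuron and neural crest list, Tubb3 (0.39 ± 0.08) and Elavl4 (0.90 ± 0.30, n = 4) were past the threshold above 0, each at 1 of several probes that reached down to -0.05 and -0.02, and Ncam1 (-0.38 and -0.44) was past it under 0, of 10 measured genes. Of 8 leukocyte genes, Cd53 was past it above 0 (0.71 ± 0.12, n = 5) and C1qa under 0 (-0.40 ± 0.18). Of the Cd53 ratios, 80% were quotients of small whole numbers. Of 19 mesenchyme genes, only Sparc (-0.31 ± 0.08) was past the threshold, and of 11 erythroid genes only Hba-a1 (0.40 ± 0.19), at 1 of 17 probes that reached down to -0.39. None of 10 epithelium and duct genes, 8 endothelium genes and 9 stomach and intestine genes passed, the members with the smallest p being Cldn7 (0.35), Sox7 (-0.32) and Tff1 (-0.32). Adjusted camera p for these 7 lists were 0.65 for neuron and mesenchyme, 0.416 for leukocyte and endothelium, 0.886 for erythroid and 0.867 for epithelium and for stomach. Adjusted over the list alone, 3 neuronal genes passed above 0 and 1 under 0, 1 leukocyte gene above 0 and 3 under 0, 2 mesenchyme genes and 1 endothelium gene under 0, and 0 in the others.

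Nrarp (-0.33 ± 0.07) was the one Notch pathway gene of 15 past the threshold, with its other probe at 0.21, and Gsk3b the one Wnt pathway gene of 14, with adjusted camera p of 0.867 for both lists. Nr4a1 (0.43 ± 0.13) was past the threshold above 0 and Ier3 (-0.37 ± 0.13) under 0 among 7 immediate early and heat shock genes (adjusted p 0.65). Of 63 genes with symbols of cytoplasmic ribosomal proteins, which by that rule took in Rps23rg1 and Rps19bp1 that do not encode any, 3 were past the threshold on each side, such as Rps24 (0.93 ± 0.20, n = 5), Rps19 (0.32 ± 0.08), Rps4x (-0.81 ± 0.22) and Rpl10 (-0.36 ± 0.14), each at 1 of several probes, with others at -0.07 for Rps24 and 0.16 for Rps4x. Of the ratios of the Rps24 probe at 0.93, 60% were quotients of small whole numbers. Rps23rg1, at -0.39, was 1 of those under 0, and the adjusted p of the list was 0.65. Of the 3 SoxC genes, Sox11 was past the threshold at 1 of 10 probes, at -0.71, while the mean over its probes was 0.16 (adjusted p of the list 0.892). In the list of X inactivation and chromosome Y, too small to test, Eif2s3y was past the threshold at -0.87 ± 0.28, and its other probe was at -0.59 with an adjusted p of 0.0545. Whether the pools differed in embryo sex could not be decided, since X-linked genes that escape inactivation lay on both sides of 0. Adjusted over the list alone, 2 Notch genes passed under 0, 1 Wnt gene above 0, 2 immediate early genes above 0 and 1 under 0, 1 ribosomal gene on each side, Sox11 at a probe under 0, and 1 gene of the X and Y list on each side. The median, mean and test differed in sign for the progenitor, mesenchyme, erythroid, stomach and intestine, SoxC, cell death, Notch and Wnt lists.

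The number of probes past the threshold fell when any 1 array was left out: without array 1, 2, 3, 4, 5 or 6 it was 16, 849, 32, 10, 8 or 13. Probes at an unadjusted limma p under 0.05 fell less, from 5868 to 5123, 5009, 4846, 4768 and 4700 without array 1, 3, 4, 5 or 6. Without array 2 they numbered 6037. Array 2 had the widest spread, with a median absolute deviation of 0.545 against 0.27 to 0.442 on the others. The probes that passed in each of these 6 fits were 3 of Afp and 1 each of Acin1 (the probe with array values close to Afp), Fabp4, Mt2 and an unnamed probe, ZX-00142F04, at 0.96. The Neurog3 probe ZX-00126H08 passed in 1 of these 6 fits, and the Ins2 probes MMC01B05 and ZX-00125L01 in 1 and 0. Their means stayed within -0.77 to -0.67, 0.45 to 0.58 and 0.50 to 0.62. Arrays 1 and 2 correlated with each other (Spearman's rho across probes, which are not independent replicates, 0.52) and arrays 3 to 6 among themselves (0.44 to 0.58), against 0.06 to 0.32 between these sets. With limma, arrays 3 to 6 alone gave 11 probes (6392 at an unadjusted p under 0.05), and arrays 1 and 2 alone gave 0 (2960). The set as a term gave 694, of which 552 were among the 1166. Without median centring, 849 probes were above 0 and 409 under 0, 67.5% above 0 against 35.7% with centring.

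**Figure D3:**
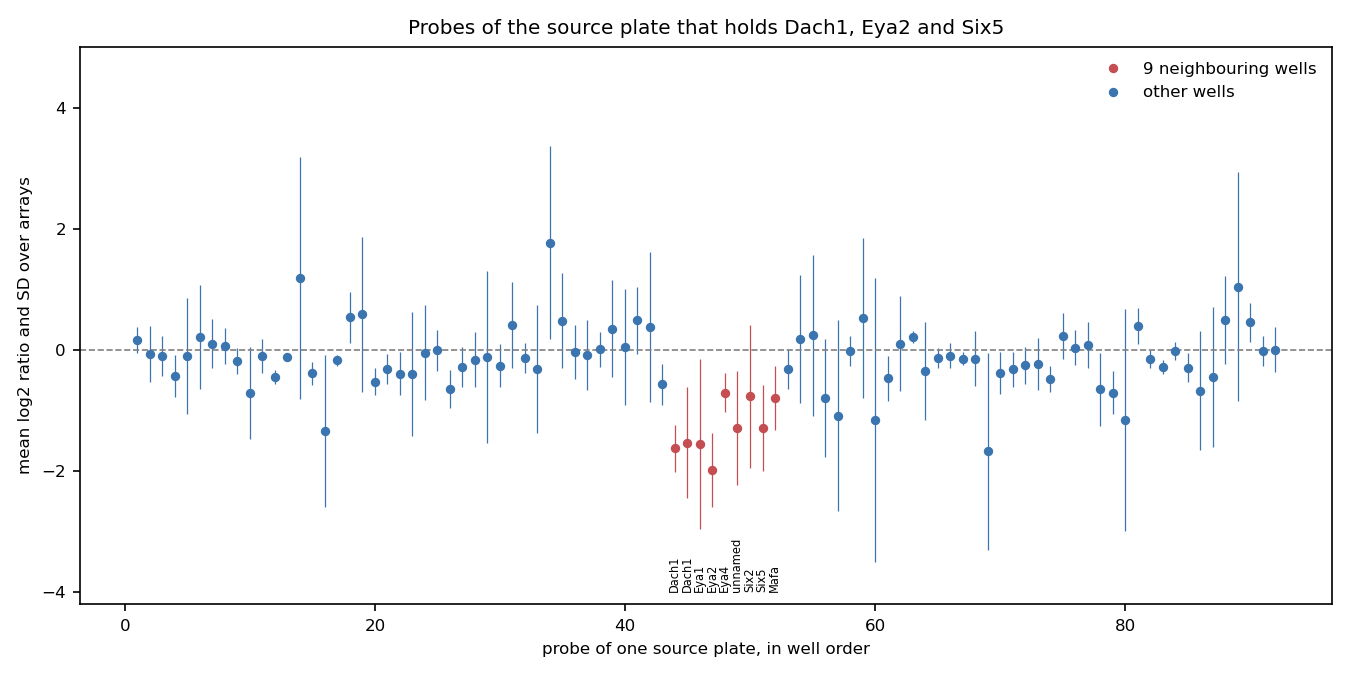
Mean log2 ratio with its SD over arrays (y axis) for the 92 tested probes of 1 source plate in well order (x axis). The 9 neighbouring wells in red, from Dach1 to Mafa, have a median of -1.29, and the other probes of the plate have a median of -0.11.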

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

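Each named probe measured on 4 or more arrays, each array measure and each list median was checked for an array far from the others relative to the whole range. Chance alone picks about 1 in 20. Of 105 named probes, 8 had such an array, and so had 1 of 25 array measures and list medians.

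The Sox4 probe MMC03H11 was at -0.35 on array 3, against -0.10 to 0.002 on the others. The Neurog3 probe MMC02E09 was at 0.32 on array 3, against -0.56 to -0.27, and the Pdx1 probe MMC02C07 was at -1.03 on array 2, against -0.19 to 0.22. The Sox11 probe MMC03H08 was at 4.01 on array 5, against 0.22 to 0.62. The Clps probe ZX-00129I19 was at -0.42 on array 3, against -1.15 to -0.89, and the Clps probe ZX-00129G15 was at -0.21 on array 2, against -0.92 to -0.70. The Sparc probe ZA-00026J22 was at -0.15 on array 1, against -0.36 to -0.30. The Fgb probe ZX-00135H16 was at -0.60 on array 2, against -1.28 to -1.08. The median of the hypoxia and glycolysis list was -0.22 on array 3, against -0.15 to -0.12.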

How the results depend on the processing

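Tests on the ceiling, the array sets and the whole-number quotients were chosen after seeing the data. The 1166 probes past the threshold (416 above 0, 750 under 0) changed with the arrays used: leaving out 1 array in turn gave 8 to 849 probes, 2 to 269 above 0 and 6 to 580 under 0. The lost degrees of freedom are not the whole cause, since the same loss left 849 without array 2 and 8 without array 5. Array 2 had the lowest array weight, 0.37 against 0.74 to 2.35 for the others. Arrays 3 to 6 gave 11 (1 above, 10 under), with 6392 probes at an unadjusted limma p under 0.05. Arrays 1 and 2 gave 0 (0 above, 0 under), with 2960 probes at an unadjusted limma p under 0.05. The array set as a term gave 694 (402 under 0), of which 552 were among the 1166, and 31 named probes lost the threshold. Between the sets, limma found 0 probes that differed, with 3269 at an unadjusted p under 0.05. The test against a log2 change of 0.2 gave 37 (9 above, 28 under), and 1 value per gene gave 630 (255 above, 375 under). Scale normalization gave 1786 (1191 under 0), array weights 2402 (892 above, 1510 under), no centring 849 above and 409 under, and leaving out probes of whole-number quotients 1129 under 0. Quantile normalization gave 1720, and probes with a value on all 6 arrays gave 1678 of 18178 tested. Probes on at least 2 arrays gave 1029, robust eBayes 1070 and the kept ceiling 1112. In none of the settings that tested probes singly against 0 was a probe of the 1166 called with the opposite sign. For settings that leave out or reweight arrays this was nearly fixed in advance, since 1159 of the 1166 had the same sign on every measured array. Except where stated, the cause of the changed counts was not tested.

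The lists past the threshold numbered 1 in all settings except 0 with an estimated correlation, where the liver list had an adjusted p = 0.158, and 2 on arrays 1 and 2, where ribosomal proteins joined at 0.20; leaving out 1 array gave 1 each time. Over its other settings the liver list had an adjusted p of 4.13e-07 to 0.0377. By a mean of at least 0.5 in size, 9 of 20 liver probes were under 0 and 0 above.

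Sox4 probe MMC02H11 was at 0.078 without centring, 0.13 on arrays 1 and 2, 0.012 with the set as a term, and -0.11 to 0.040 leaving out 1 array; MMC03H11 was at 0.012 without centring and -0.11 to -0.040 leaving out 1 array. No Sox4 value passed the threshold.

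With the ceiling kept, the Dach1 probe MMC02D12 turned to 1.99, since 1 of its values was then the ceiling. The other sign changes were of probe means, or of the direction of a list's test, near 0 or past no threshold. The list medians given below did not all change sign. Those of cell cycle, mesenchyme and Wnt kept it, as did SoxC at -0.019 and -0.025. Without centring, Sox11 ZA-00029D21 was at 0.021, Gcg ZX-00126B21 at 0.074, Sox12 at 0.084 and the erythroid median at 0.10. Gcg MMC01B12 was at -0.0092 with scale, -0.0070 with quantile normalization, -0.024 with array weights, -0.003 with the ceiling kept and -0.086 on arrays 3 to 6. With array weights, Pdx1 MMC02D08 was at -0.096, Gcg ZX-00126B21 at 0.00077, Sox12 at 0.012, and the test of epithelium (median 0.00012), cell cycle (0.046) and ribosomal proteins (0.0029) turned. On arrays 3 to 6, Pdx1 probes were at 0.064, -0.052 and -0.079, Sox11 PX-00626H22 at -0.036, Sox12 at 0.069, and list medians at -0.061 for epithelium, 0.035 for cell cycle, -0.011 for immediate early and -0.027 for ribosomal genes. On arrays 1 and 2, Sox11 probes were at -0.064 and 0.11, Neurod1 ZX-00118A09 at 0.030, Gcg ZX-00126B21 at 0.063, and medians at 0.066 for mesenchyme, 0.099 for erythroid, 0.039 for SoxC and 0.021 for Notch. The erythroid median was 0.025 with the set as a term and 0.047 with 1 probe per gene, where SoxC was at -0.025, Notch at 0.10 and Wnt at -0.088. On probes of all 6 arrays SoxC was at -0.019, and without whole-number quotients epithelium was at -0.0071.

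Leaving out 1 array, signs turned within -0.060 to 0.063 for Gcg MMC01B12, -0.063 to 0.017 for ZX-00126B21, -0.24 to 0.012 and -0.28 to 0.27 for Pdx1 MMC02C07 and MMC02D08, -0.0036 to 0.067 for Sox11 PX-00626H22, and -0.090 to 0.059 for Sox12. The lists whose test turned direction had medians of 0.047 to 0.090 for cell cycle, 0.0032 to 0.068 for ribosomal, -0.014 to 0.076 for epithelium, -0.032 to 0.021 for erythroid and -0.030 to 0.059 for SoxC. Among named probes, 1179 comparisons with a setting kept their side of the threshold and direction, 591 lost the threshold, 11 gained it and 30 changed sign. Among lists, 370 kept both, 1 lost it, 1 gained it and 28 changed the direction of the test. Signal over background is unknown here and limits the ratios of dim spots. Each ratio sets both RNAs against each other on 1 array, so the test against 0 is itself paired by array.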

Other observations

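The tests of the liver list, of the sex-linked genes and of the sign patterns were chosen after their results had been seen. A test against a log2 change of 0.2 rather than 0 left 37 probes, 28 under 0 and 9 above. Besides genes already named it held, among others, Serpina1e, a secreted protease inhibitor of liver, at -1.14, Lyve1, a receptor of lymphatic and embryonic endothelium and of macrophages, at -0.74, Stat3, a transcription factor downstream of cytokines, at -0.79, and Akr1c12, an aldo-keto reductase, at -0.77. Cystm1 was under 0 at 2 probes, at -0.81 and -0.84. Above 0 were, among others, Cdc6 at 0.79, Anp32a at 0.95 and Plekho1 at 0.94.

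Of the 32 sign patterns of the 6 arrays, 1, the real one, gave as many as its 1166 probes past the threshold, and the highest of the others gave 0. This excludes chance signs only if the 6 arrays are independent. Arrays 1 and 2 and arrays 3 to 6 correlated as sets and the arrays can be repeats of 1 pool per genotype, so chance between animals is not excluded. A bias between channels shared by all arrays is not excluded either.

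Of 12 liver genes, Apoc3 (0.13), Apoh (0.08) and Hpx (0.03) had means above 0 and the others under 0. The median on the array with the highest value was -0.319, which argues against a part of the arrays as the source. Liver tissue carried into the pool labelled wild type could account for the liver genes under 0, if the ratio is knockout over wild type. The list median was -0.394 (bootstrap standard error 0.229), where the test asked for -0.5 or less. It was -0.56 on arrays 3 to 6, -0.50 on probes of all 6 arrays and -0.25 with 1 probe per gene. The test also asked for a clearly lower erythroid median, since fetal liver makes blood. The erythroid median was -0.00079, so this condition was not met, though blood in both pools would hide a small share. Alb at -0.29 lay far from Afp, Ttr and Rbp4 are also made in islet cells, and levels were not analysed here. Dissection and an effect of Sox4 on these genes cannot be told apart.

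Of the probes past the threshold at 1 or more in size, 68 were above 0 and 30 under 0. Probes past the threshold at 1 or more had 34.1 percentage points more whole-number quotients than those at -1 or under (bootstrap standard error 7.22; permutation p 1e-04, the smallest the draws can give). This is consistent with dim spots, at which few intensity units set the ratio, as the source of many of these values. An effect of Sox4 on single genes among them was not tested.

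Probes of Dach1, Eya2, Six5 and related genes lay under 0 in neighbouring wells. On other source plates, 2 probes of these families had a median of 0.82, Six6 at 1.27, on 4 arrays with 75% of its ratios whole-number quotients, and Eya4 at 0.37, neither past the threshold, against -0.71 for Eya4 within the wells. A shared plate position may therefore underlie the block, though 2 probes are few and 1 of them is of this kind. An effect of Sox4 on this gene family was not tested apart from the plate.

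Xist was at 0.32 and 0.33, past the threshold at neither probe, and Eif2s3y at -0.87 and -0.59. The X-linked genes that escape inactivation had a median of 0.22 and lay on both sides of 0: Ddx3x at 0.22, Kdm5c at 0.01 and 0.71, and Eif2s3x at -0.32. The signs of Xist, Eif2s3y and this median were those predicted for a different share of male and female embryos in the pools. With escape genes on both sides of 0, and a prediction written after the values were seen, the question stayed open. Of the 100 measured genes nearest to Sox4 in order on chromosome 13, 11% were past the threshold against 8.2% on other chromosomes, a ratio of 1.34 (95% interval of the odds ratio 0.664 to 2.61, Fisher's exact p 0.275). This asked whether sequence differences of the strain that carried the mutant allele had moved probes near the gene. The interval is too wide to decide. Serpinb9c, among the largest ratios above 0, was past the threshold in this stretch.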
